A study of Cavia porcellus with 2 samples.

How the data were processed

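Primary visual cortex of male guinea pigs was profiled by droplet single-cell RNA sequencing (10x Genomics 3' v3.1 chemistry, with UMIs). There were 2 libraries, 1 of normal controls and 1 of animals under form deprivation for 4 weeks (age 2 to 6 weeks), each made from 6 animals, and no map from cells to animals was used here, so each group is 1 sample. The deposited values are raw UMI counts per gene and cell barcode, made with Cell Ranger 7.0.0 per the file headers of both libraries, whereas the submitters' processing notes list Cell Ranger 3.1.0 and R 4.3.1. The genome build and annotation are not given in the sources used here. The lowest total of a deposited barcode was 500 UMIs in the control and 501 in the form deprivation library, with the depth of each library given at the start of the results. Neither cell type labels nor a genome sequence were used here.

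The files list 31585 features, of which 16761 had a gene symbol. Of 15204 features with a LOC identifier, 12669 were found in the reference table of gene names (assembly mCavPor4.1, used only for names), which gave 404 of them a symbol. Features with a symbol held 88.5% of control and 86.7% of form deprivation UMIs, so genes known only by a LOC identifier are missing from lists and markers. Among them are most haemoglobin features, which therefore stayed in the total that was meant to exclude haemoglobin. There were 83 ribosomal protein genes and 13 mitochondrially encoded genes.

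Cells with at least 500 detected genes and at most 20% mitochondrial UMIs were kept, which removed 712 control and 540 form deprivation barcodes. Doublets were scored per library with Scrublet as implemented in scanpy, and the cells with the highest scores were removed at an expected rate of 0.8% per 1000 barcodes, 1608 control barcodes (11.3%) and 1146 form deprivation barcodes (9.58%), counted over all deposited barcodes, of which 79 and 35 had also failed the cell filter. The automatic threshold marked 760 cells (5.36%) and 518 cells (4.33%). Of the barcode sequences, 59 occurred in both libraries. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 34 clusters over both libraries, without batch correction.

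Clusters were named from marker genes fixed before the data were examined, as were the gene lists, the rules for naming genes, the filters and most of the alternatives. The rule that scores clusters was set after the data were examined: a mean log2 fold of a class's markers over the median cluster of at least 1 (with a pseudocount of 20 CPM), a lead of at least 0.3 over the next class and at least 3 raised markers. Clusters with a median depth under 1/3 of that of their sample and no marker among their 10 leading genes, or with leading genes against the name, stayed unnamed. Class shares have exact (Clopper-Pearson) 95% binomial intervals, and a count of 0 has a floor of 3 cells.

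For each of 8 classes with at least 100 cells in each library, counts were summed per library and divided by the class total to give CPM. Ratios (form deprivation over control) have exact conditional 95% intervals, and sums have exact Poisson intervals. These intervals, and those of the shares, cover counting error only. No test between conditions, p-value or count of changed genes was made, because each group is 1 library. For each of 35 gene lists, the median log2 ratio of members with at least 20 counts over both libraries was taken where at least 5 members were measured. Its interval came from 2000 resamples of the members with redrawn Poisson counts, so it covers the spread between members as well as counting error. The median was placed among 10000 random lists of the same size, matched on mean expression in 10 bins. A list is described in a class where its median lay in the highest or lowest 2.5% of random lists, or where it had been assigned to that class beforehand. Lists meant for all classes, such as glycolysis, are described only where they lay in those tails or, for the heat shock list, beside the microglial results, and otherwise by their range where they lay in none.

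The named genes are, in the 5 largest classes, the 6 higher and the 6 lower genes with the largest ratio at the bound of the interval nearest to no difference, among genes with a symbol, at least 50 CPM in a library and at least 100 counts over both, and 3 in each direction in the other classes. From each described list, 2 to 4 of the members with the most counts in the class could also be named. Leading genes of clusters, Cd74 and C1qa as microglial genes counted in other classes, Gria2 in precursors and the features known only by an identifier stand outside that rule and were chosen after their values were seen. A few genes that the rule or a list would have named are not reported here. A ratio of 1.5 is a description and not a threshold of a test.

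The alternatives were no cell filter or a stricter one (1000 genes, 10% mitochondrial), no doublet removal or the automatic threshold, resolutions of 0.5 and 2, each library clustered separately, ratios centred on the median of all genes, TMM factors (edgeR 4.0.16, used only for these), totals without mitochondrial, ribosomal protein and haemoglobin genes, the mean of each cell's own CPM, cells thinned to 2000 UMIs (leaving out 924 control and 770 form deprivation cells, with a median of 1237 and 1240 genes after thinning against 2849 and 2948 before), at least 100 counts per list member or 1 in each library, a pseudocount of 10 CPM, and shares without unnamed clusters or within neurons and ectoderm-derived glia. Depth and quality were read over all barcodes as well as kept cells. Alternatives chosen after the data had been examined left out, for named genes, the 10 cells of each library with the most UMIs of the gene, and, for genes and lists in microglia-like cells, the clusters of which a library held under 10% of the cells. Microglia-like cells were the only compared class with such clusters.

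The intervals and list comparisons were tested on simulated counts drawn from the real means and totals, with 200 changed genes. In microglia-like cells (14066 genes) the intervals covered the true ratio for 95.7% of unchanged genes, and 5% of 200 random lists fell outside the middle 95%. In border macrophage-like cells (6805 genes) the shares were 96.1% and 4.5%, with 96.5% coverage of changed genes. Class sums were drawn independently for each gene, the setting the intervals assume, so these shares check the calculation only. UMIs gathered in a few cells and correlated genes of a list were not simulated. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.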

Results

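Single-cell transcriptomes were collected from the primary visual cortex of young male guinea pigs (Cavia porcellus), a species in which covering or blurring an eye during growth lengthens the eye and makes it short-sighted (form deprivation myopia). Animals were 2 weeks old at the start and were kept for 4 weeks with normal vision or under form deprivation. Each group is 1 droplet library made from 6 animals, so there is no replicate and no test between the conditions: every ratio below compares these 2 libraries. Intervals of shares and of genes are 95% intervals of counting error only. Those of list medians also cover the spread between the genes of a list. No interval covers the spread between animals. The control library held 14178 barcodes with 113423318 unique molecular identifiers (UMIs), and the form deprivation library held 11967 barcodes with 98306549 UMIs. Median depth per barcode was 7172 and 7461 UMIs, with 2848 and 2955 detected genes, and the median mitochondrial share was 0.676% and 0.749%. After filtering and removal of expected doublets, 11937 control cells (median 6974 UMIs) and 10316 form deprivation cells (median 7296 UMIs) were kept. They formed 34 clusters, named from marker genes as microglia-like, astrocyte-like and so on.

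The first comparison asks which cell types made up the cortex of the deprived and the control animals. Microglia-like cells, the resident immune cells of the brain, were 40.9% of control cells (40.0 to 41.7%) and 25.3% of form deprivation cells (24.4 to 26.1%), a ratio of 0.618 (0.589 to 0.648). Astrocyte-like cells, which take up glutamate and feed neurons, were 18.5% of control and 25.4% of form deprivation cells, a ratio of 1.37 (1.30 to 1.45). Myelin-forming oligodendrocyte-like cells were 9.96% and 12.3% of cells, a ratio of 1.24 (1.14 to 1.34), whereas their dividing precursors, the oligodendrocyte precursor-like cells, were 12.7% and 8.62%, a ratio of 0.679 (0.624 to 0.738). The cells of small vessels were higher in the form deprivation library: endothelial-like cells, which line the vessels, were 4.23% and 8.67%, a ratio of 2.05 (1.83 to 2.29), and mural-like cells (pericytes and smooth muscle) 1.69% and 3.47%, a ratio of 2.05 (1.72 to 2.45). Shares within a library are not independent, so the lower microglia-like share by itself raises the others. Within neurons and ectoderm-derived glia, which leaves out microglia-like cells, the ratio was 1.17 for astrocyte-like and 1.05 for oligodendrocyte-like cells. For oligodendrocyte precursor-like cells it was 0.577. Shares of vessel cells without microglia-like cells were not computed.

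Among blood-derived and border cells, neutrophil-like cells were 3.07% and 2.81% of cells and border macrophage-like cells 0.947% and 0.969%, and the intervals of both ratios included 1. T or NK-like cells were 1.06% and 0.553%, a ratio of 0.523 (0.376 to 0.721), which became 0.844 when no doublets were removed. Monocyte or dendritic-like cells were 0.578% and 0.640%, and cycling-like cells 0.276% and 0.543%. The cycling-like cluster was led by the division genes Mki67 and Top2a but also by the neutrophil granule genes Pglyrp1 and Camp. With a stricter cell filter the neutrophil-like ratio became 1.18 and the oligodendrocyte precursor-like ratio 0.365, because a cluster that held 269 control and 481 form deprivation precursor-like cells was then left without a name.

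Cells resembling neuroblasts, the migrating precursors of neurons, formed a cluster of 171 cells that all came from the form deprivation library, 1.66% of its cells (1.42 to 1.92%). None of the 11937 control cells lay in it. The exact interval of the control share reached up to 0.0309%, and the lower bound of the ratio was 53.1. Against the floor of 3 cells, a control share of 0.0251%, the form deprivation share was 66.0-fold higher. The cluster that held the same 171 cells had 28 control and 233 form deprivation cells when no doublets were removed, 13 and 224 with the automatic doublet threshold, and 32 and 227 at a clustering resolution of 0.5. It stayed unnamed under both doublet alternatives. At resolution 0.5 it was named cycling-like, because it merged with the cycling-like cells. Ependymal-like cells, the ciliated lining of the ventricles, were 44 form deprivation cells and 1 control cell, a ratio of 50.9 (8.67 to 2056). A cluster held by 1 library can be that library and not a cell type, and both classes are weighed in the closing section. Clusters without a name held 6.12% of control and 8.64% of form deprivation cells. The thresholds that leave a cluster without a name were set after the data had been examined, and tissue dissociation can set all of these shares.

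**Figure D1:**
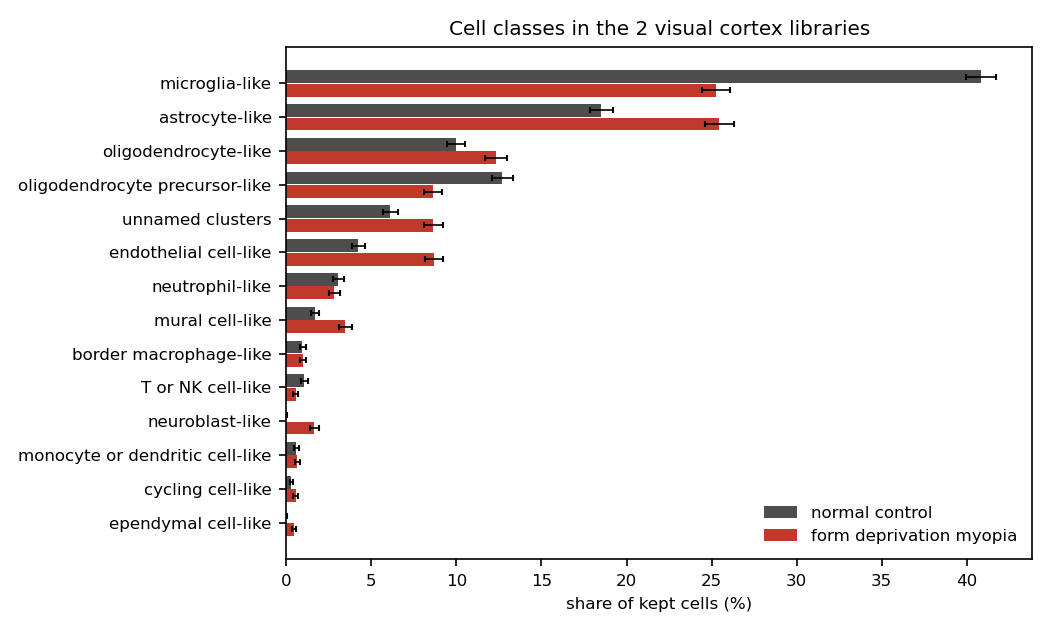
Bars give the share of kept cells (%) in each class for the normal control library (grey) and the form deprivation library (red), 1 library each, with exact 95% binomial intervals for counting error. Microglia-like cells were 40.9% of control and 25.3% of form deprivation cells, and endothelial-like cells 4.23% and 8.67%.

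No cluster of mature neurons was recovered from either library. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, had 29 UMIs over all kept control cells and 36 over all kept form deprivation cells, or 0.317 and 0.453 CPM (UMI counts scaled to the total of all kept cells of the library here, and of the cells of a class below). Gad1, a GABA-synthesising enzyme of inhibitory neurons, had 229 and 253 UMIs. Gene lists intended for neurons were therefore read in glia, vessel cells, neutrophil-like and border macrophage-like cells, 8 classes in all, each with at least 100 cells in both libraries.

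The second comparison asks which genes and pathways differed within a class. In microglia-like cells (4877 control and 2605 form deprivation cells, median 6935 and 7720 UMIs) the genes with the largest higher ratios included Tnfsf9 and Tnf. Tnfsf9, the ligand of the co-stimulatory receptor 4-1BB, was 21.4 CPM in control and 77.7 CPM in form deprivation, a log2 ratio of 1.86 (1.73 to 1.99). Tnf, the tumour necrosis factor gene, was 144 and 476 CPM, a log2 ratio of 1.73 (1.68 to 1.78). Dusp2, a phosphatase acting on MAP kinases, the interferon-induced Isg15, the receptor adaptor Traf1 and the small GTPase Rrad had log2 ratios of 1.46, 1.43, 1.41 and 1.37. Genes with the largest lower ratios were Agpat4, an acyltransferase of phospholipid synthesis, at 96.6 and 1.74 CPM (log2 ratio -5.80, -6.32 to -5.32), Grik1, a kainate receptor subunit, at 71.0 and 1.29 CPM (-5.78), and Prkcb, protein kinase C beta, at 64.1 and 6.81 CPM (-3.24). Only 7.79% of control microglia-like cells held an Agpat4 UMI, 19.0% a Grik1 UMI and 18.0% a Prkcb UMI. With a pseudocount of 10 CPM these log2 ratios were -3.18, -2.84 and -2.14. Adgre1, the macrophage surface protein F4/80, Naaladl2, and Ciita, the master regulator of MHC class II genes, had log2 ratios of -1.88, -1.83 and -1.75.

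The 2 libraries filled the clusters of microglia-like cells unevenly. Cluster 1, led by the heat shock genes Dnajb1 and Hspa6, held 19.5% of control and 50.4% of form deprivation microglia-like cells, and cluster 2, led by Tnf, Sod2 and Il1b, held 20.7% and 38.8%. Cluster 4, led among others by the chaperone regulator Bag3, held 31.0% and 0.384%, and cluster 10, led by Nr4a3 and Adgre1, held 950 and 39 cells. Cluster 13, led by Bag3 and P2ry12, held 9.29% and 8.91%. Values that include a leading gene of a cluster, such as Tnf and Adgre1, therefore also carry the make-up of the class. Within clusters 1, 2 and 13, Tnf had log2 ratios of 1.28, 0.85 and 2.52, Agpat4 -6.60, -5.51 and -4.12, Grik1 -2.30, -5.02 and -2.12, Prkcb -0.17, -1.65 and -0.57, and Isg15 1.64, 0.29 and 2.08. In cluster 13 the values of Agpat4 and Grik1 each rested on 2 form deprivation UMIs. Over these 3 clusters together, an alternative added after the data had been examined, the log2 ratio of Tnf was 0.99, of Tnfsf9 1.25, of Traf1 0.63, of Grik1 -4.13, of Prkcb -1.32, of Naaladl2 -0.97, of Adgre1 -1.12 and of Ciita -0.44. In the separate clusters Ciita had log2 ratios of 0.32, -0.82 and 0.27, so its direction was not shared. Over clusters 1, 2 and 13 together Isg15 was 0.92. In the whole class its log2 ratio was 2.14 and 2.13 at clustering resolutions of 0.5 and 2. It was 2.18 without doublet removal and 2.19 with the automatic doublet threshold, against 1.43 as reported. The class held 5040 control and 2909 form deprivation cells at resolution 0.5, and which cells raised the ratio was not tested.

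Among the gene lists fixed before the data were examined, those of inflammation and of early response were higher in form deprivation microglia-like cells. Of 19 measured inflammatory cytokines and NF-kB targets, 6 were above 1.5-fold higher, 1 was lower and 12 lay between, with a median log2 ratio of 0.39 where 95% of expression-matched random lists fell between -0.36 and 0.15. Nfkbia, the inhibitor that NF-kB itself induces, was 1581 and 3611 CPM, and Cd83 1726 and 2239 CPM. Of 24 immediate early genes 8 were higher, 1 was lower and 15 lay between (median 0.38), with Fos at 2693 and 3298 CPM and Dusp1 at 2075 and 2847 CPM. Within clusters 1 and 2 these medians were far smaller, -0.07 and 0.04 for the inflammatory list and 0.04 and 0.18 for the immediate early genes, whereas cluster 13 gave 0.76 for the inflammatory list and -0.03 for the immediate early genes. The heat shock and dissociation stress list, which tissue handling can raise, had a median of 0.12, inside the range of random lists. Yet cluster 1, led by heat shock genes, held 19.5% of control and 50.4% of form deprivation microglia-like cells. The list median therefore does not separate the inflammatory and immediate early medians from an effect of handling, which was not tested.

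Genes of the disease-associated microglial state were also higher, with 6 of 18 above 1.5-fold, 3 lower and 9 between (median 0.36), and here clusters 1, 2 and 13 gave 0.55, 0.47 and 0.30. Apoe, the lipid carrier, was 17510.0 and 23510.2 CPM, Tyrobp, the adaptor of the receptor Trem2, 2053 and 2509 CPM, and the lysosomal protease Ctsb 1739 and 2444 CPM. The unfolded protein response (2 of 19 higher, median 0.30) was led in size by Hspa5, the chaperone BiP, at 939 and 1744 CPM. Autophagy and lysosome genes (median 0.27, 1 of 24 higher and 2 lower), ribosomal proteins (median 0.32, 2 of 82 higher), glycolysis (0.18, 5 of 20 higher), endothelial activation (0.19, 5 of 15 higher and 2 lower) and nuclear-encoded oxidative phosphorylation (0.13, none of 38 past 1.5-fold) also lay above the middle 95% of random lists. Gapdh, of glycolysis, was 563 and 875 CPM, and Icam1, a leukocyte adhesion molecule, was 845 and 1733 CPM. In clusters 1, 2 and 13 the endothelial activation median was 0.35, 0.35 and -0.16 and that of glycolysis 0.33, 0.30 and 0.02. Synaptic vesicle release had a median of 0.16, with 1 of 16 higher and 3 lower, -0.20 within cluster 2, and -0.06 after thinning every cell to 2000 UMIs.

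Lists that define resting microglia differed little between the libraries. The homeostatic list had a median of -0.09, with P2ry12, a purinergic receptor of surveying microglia, at 1399 and 1260 CPM and Csf1r, the receptor for their survival factor, at 1129 and 1058 CPM. Of 15 members 1 was lower and none was higher. The interferon response had a median of -0.04, with 4 of 14 members higher, 1 lower and 9 between. Bst2, a membrane protein that tethers budding viruses, was 120.2 and 155 CPM, and Ifih1, a sensor of viral RNA, 57.2 and 95.9 CPM. Both medians change sign when ratios are centred on the median of all genes, which was -0.12 in this class. Complement (median -0.19) held the subunits C1qa at 1433 and 2020 CPM and C1qc at 877 and 1402 CPM, against 4 of 13 members that were lower, and its median was 0.05 without clusters 4 and 10. Antigen presentation (-0.25, none of 12 higher and 4 lower) and cell cycle genes (-0.20, 2 of 17 higher and 2 lower) lay inside the range of random lists. The direction was not shared between clusters: in clusters 1, 2 and 13 antigen presentation had medians of 0.48, -0.17 and 0.24, interferon response 0.39, -0.15 and 0.52, complement 0.33, -0.15 and 0.27, and cell cycle genes 0.15, 0.15 and -0.07. When each library was clustered separately, the cell cycle median was 0.52. The lowest medians were those of ionotropic glutamate receptors (-0.88, 6 of 10 lower) and postsynaptic scaffold genes (-0.80, 10 of 17 lower and 3 higher). Gria2, an AMPA receptor subunit, was 7.75 and 4.72 CPM in microglia-like cells and 893 and 952 CPM in oligodendrocyte precursor-like cells.

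**Figure D2:**
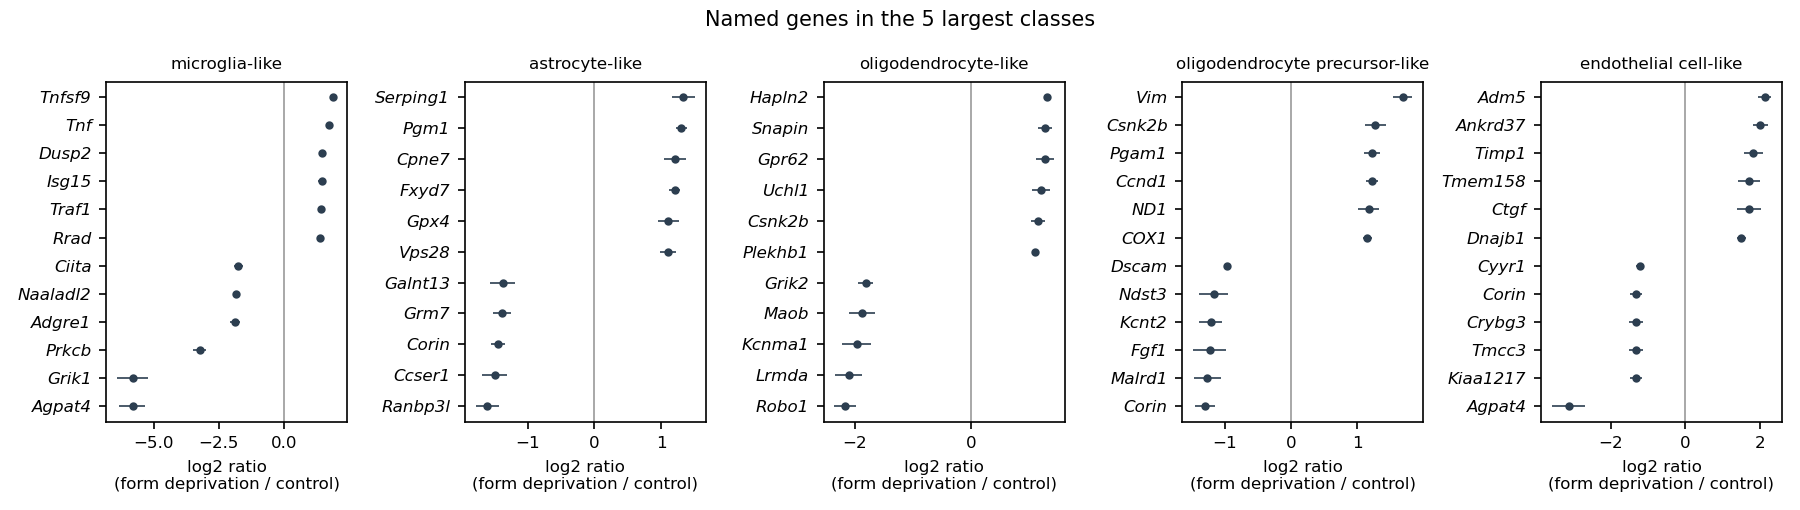
Points give the log2 ratio of CPM (form deprivation over control, 1 library each) of the up to 6 reported genes with the largest higher and up to 6 with the largest lower ratio in each of the 5 largest classes, with 95% intervals of counting error as lines. The scale differs between panels, and Agpat4 at -5.80 in microglia-like cells lies farthest from 0.

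In astrocyte-like cells (2211 control and 2625 form deprivation cells, median 6865 and 6671 UMIs) the lists of energy metabolism, ribosomal proteins and reactivity were higher and those of glutamate receptors lower in form deprivation, with most of these medians closer to 0 within clusters. Pgm1, which links glycogen to glycolysis, was 93.5 and 230.0 CPM, a log2 ratio of 1.30 (1.21 to 1.38), and Fxyd7, a regulator of the sodium pump, 105 and 241 CPM (1.20). Serping1, the inhibitor of complement C1, Cpne7, the endosomal sorting gene Vps28 and Gpx4, which removes lipid peroxides, had log2 ratios of 1.33, 1.21, 1.10 and 1.10. Within clusters 6, 7, 8 and 15 of this class Serping1 was 0.74, 1.16, 0.87 and 0.08, Vps28 0.78, 0.42, 0.72 and 0.57, and Gpx4 0.79, 0.74, 0.56 and -0.08. Corin, the protease that activates natriuretic peptides, was 159 and 58.8 CPM (-1.44, -1.54 to -1.33), and Grm7, a metabotropic glutamate receptor, had a log2 ratio of -1.38. Ranbp3l, Ccser1 and the glycosyltransferase Galnt13 had log2 ratios of -1.60, -1.49 and -1.37.

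Ribosomal protein genes had a median log2 ratio of 0.64 in astrocyte-like cells, with 56 of 82 above 1.5-fold higher, 1 lower and 25 between. Glycolysis (median 0.51, 7 of 19 higher and 1 lower) included Gapdh at 1298 and 2282 CPM and Aldoc at 1299 and 2274 CPM, and oxidative phosphorylation (0.45, 10 of 38 higher) included Atp5f1b, a subunit of ATP synthase, at 285 and 448 CPM. The reactivity list had a median of 0.47, with 6 of 18 higher and 2 lower. Its intermediate filament gene Vim was 107 and 211 CPM and the small heat shock gene Hspb1 297 and 397 CPM. Interferon response (0.40, 3 of 13 higher and 1 lower), heat shock and dissociation stress (0.37, 2 of 13 higher), autophagy and lysosome (0.34, 4 of 24 higher) and the disease-associated microglia list (0.34, 2 of 15 higher and 1 lower) also lay above the middle 95% of random lists. Hsp90aa1, a cytosolic chaperone, was 533 and 896 CPM, Stat2 48.8 and 64.2 CPM, the lysosomal protease Ctsd 291 and 475 CPM, and Apoe, which astrocytes secrete, 11531 and 14986 CPM. Cholesterol biosynthesis (median 0.20, all 20 members between the 1.5-fold bounds, Msmo1 1303 and 1365 CPM) and glutamate and ion handling (0.18, 2 of 17 higher and 2 lower) lay inside the random range. Slc1a2, the main glutamate transporter, was 14243 and 12450.0 CPM, and Glul, glutamine synthetase, 2359 and 2976 CPM.

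Immediate early genes were lower in astrocyte-like cells, with a median of -0.26 (1 of 21 higher, 4 lower), and Nr4a2, an activity-induced nuclear receptor, was 86.7 and 47.4 CPM. Ionotropic glutamate receptors had a median of -0.80 with 7 of 12 lower, metabotropic receptors -0.65 with 4 of 5 lower, and amine and adenosine receptors -0.40 with 4 of 10 lower and 1 higher. Gria2 was 549 and 453 CPM, Grm3 2939 and 1870.1 CPM, and the serotonin receptor Htr2a 83.7 and 49.4 CPM. Different clusters held most of this class: cluster 7, led by Slc4a4 and Rorb, held 51.4% of control and 11.7% of form deprivation cells, cluster 8, led by Agt and Aqp4, 17.9% and 39.0%, and cluster 6, led by Cidea and Igfbp2, 23.4% and 35.9%. Within clusters 6, 7 and 8 the ionotropic receptor median was -0.06, -0.15 and -0.07, that of ribosomal proteins 0.27, 0.31 and 0.29, and that of immediate early genes -0.45, -0.24 and -0.33. Cluster 15, of lower depth (median 1449 UMIs) and led by S100b and Aldoc, held 7.28% and 13.4% of the class and gave 0.66, -0.22 and -1.02 for the same lists. In clusters 6, 7, 8 and 15 glycolysis gave 0.21, 0.27, 0.32 and 0.09, oxidative phosphorylation 0.11, 0.10, 0.16 and -0.09, reactivity 0.49, 0.20, 0.23 and 0.02, autophagy and lysosome 0.05, 0.04, 0.20 and -0.06, and the disease-associated microglia list -0.08, 0.29, 0.02 and -0.37. Heat shock and dissociation stress (0.05, 0.06, 0.17 and -0.28) lay inside the random range in each of these clusters, and so did interferon response (0.17, 0.24 and 0.26) and the amine and adenosine receptors (-0.15, 0.11 and 0.12) in clusters 6, 7 and 8, where they could be computed. With at least 100 counts per member the ionotropic median was -0.32.

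Microglial transcripts were also counted in astrocyte-like cells. Cd74, an MHC class II chain expressed by microglia, had a UMI in 45.8% of control and 22.6% of form deprivation astrocyte-like cells at median depths of 6865 and 6671 UMIs, and in 17.4% and 8.65% after thinning to 2000 UMIs. In microglia-like cells the share was 99.9% and 100%, at median depths of 6935 and 7720 UMIs and 99.9% and 100% after thinning. Beside that stand 2 list medians in astrocyte-like cells that rest on microglial genes: the homeostatic microglia list at -1.01 (8 of 14 lower), although the more abundant Cst3 was 6785 and 8573 CPM, and complement at -0.78 (8 of 14 lower and 3 higher), although C3, the central complement protein, was 68.0 and 106 CPM. After thinning the complement median was 0.08. The same list of homeostatic microglia was -1.20 in oligodendrocyte-like, -0.52 in oligodendrocyte precursor-like and -1.32 in endothelial-like cells (-0.31 in oligodendrocyte-like and -0.23 in endothelial-like cells after thinning), and Cd74 had a UMI in 55.7% and 28.8% of oligodendrocyte-like and in 49.5% and 23.8% of oligodendrocyte precursor-like cells (median depths 10980 and 9454, 7717 and 7213 UMIs). After thinning those shares were 13.3% and 8.48%, and 16.1% and 7.67%.

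In oligodendrocyte-like cells (1189 control and 1270 form deprivation cells, median 10980 and 9454 UMIs) the lists of glycolysis and oxidative phosphorylation were higher and those of glutamate receptors lower in form deprivation. Hapln2, a matrix link protein of the nodes of Ranvier, was 657 and 1622 CPM, a log2 ratio of 1.30 (1.27 to 1.34), and Plekhb1 843 and 1788 CPM (1.09). Both lead cluster 11, which held 29.2% of control and 47.9% of form deprivation oligodendrocyte-like cells, against 70.8% and 52.1% in cluster 5, led by Opalin and Ank3. Within clusters 5 and 11 their log2 ratios were 1.15 and 0.85 for Hapln2 and 1.08 and 0.90 for Plekhb1. Snapin, a binding partner of the vesicle fusion machinery, the orphan receptor Gpr62, the ubiquitin hydrolase Uchl1 and Csnk2b, the regulatory subunit of casein kinase 2, had log2 ratios of 1.26, 1.26, 1.20 and 1.14, but Uchl1 was 0.31 (-0.04 to 0.66) within cluster 5 and 0.73 within cluster 11. Snapin and Csnk2b were each above 1.5-fold higher in 6 of 7 other classes with at least 20 counts, Plekhb1 in 0 of 4. Robo1, a receptor for Slit guidance proteins, was 105 and 23.4 CPM (-2.16, -2.35 to -1.99), and Grik2, a kainate receptor subunit, 172 and 49.0 CPM (-1.81). Lrmda, the potassium channel gene Kcnma1 and Maob, which breaks down amines, had log2 ratios of -2.10, -1.96 and -1.87, that of Lrmda being -1.42 without doublet removal, and within cluster 11 they were -1.39, -1.07 and -0.95. Grik2 was -1.59 within cluster 5 and -1.12 within cluster 11.

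The myelin list had a median of 0.25 in oligodendrocyte-like cells, with 7 of 20 members above 1.5-fold higher and none lower, just inside the range of random lists (-0.30 to 0.27). Its members Mbp and Cnp were 4989 and 7334, and 5629 and 8555 CPM. Cholesterol biosynthesis, which supplies myelin lipid, had a median of -0.02 with all 20 members between the 1.5-fold bounds, and changes sign with centring on the median of all genes. Glycolysis (0.48, 8 of 20 higher and 3 lower), the unfolded protein response (0.43, 6 of 18 higher and 1 lower), oxidative phosphorylation (0.35, 7 of 38 higher), ribosomal proteins (0.32, 3 of 81 higher), heat shock and dissociation stress (0.32, 2 of 13 higher) and autophagy and lysosome (0.25, 4 of 24 higher and 2 lower) lay above the random range. Gapdh was 739 and 1230.1 CPM, the chaperone Calr 504 and 842 CPM, and Cryab, a small heat shock protein, 2282 and 4289 CPM. All 5 metabotropic glutamate receptors were lower (median -1.06), as were 6 of 12 ionotropic receptors (-0.61, 1 higher), 8 of 14 postsynaptic scaffold genes (-0.64, 1 higher) and 6 of 16 genes of TGF-beta signalling (-0.46, 2 higher). Grm3 was 933 and 518 CPM, the adhesion gene Nlgn1 1188 and 673 CPM, and the receptor Bmpr2 228 and 161 CPM. Within clusters 5 and 11 the ionotropic median was -0.55 in both.

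In oligodendrocyte precursor-like cells (1515 control and 889 form deprivation cells, median 7717 and 7213 UMIs) the cell cycle list and the mitochondrially encoded genes were higher in form deprivation. Vim, the intermediate filament vimentin, was 50.3 and 161 CPM, a log2 ratio of 1.68 (1.54 to 1.83), and Ccnd1, cyclin D1, 160.0 and 372 CPM (1.22, 1.13 to 1.31). Csnk2b, the glycolytic enzyme gene Pgam1 and the mitochondrially encoded ND1 and COX1 had log2 ratios of 1.27, 1.22, 1.17 and 1.15. Above 1.5-fold higher ratios were also seen for Csnk2b in 6 of 7 other measured classes and Pgam1 in 5 of 7. For Ccnd1 this was 0 of 6 and for COX1 0 of 7. Corin (-1.30), Malrd1 (-1.27), the growth factor gene Fgf1 (-1.23), the potassium channel gene Kcnt2 (-1.22) and the heparan sulfate enzyme gene Ndst3 (-1.17) were lower, and so was the adhesion gene Dscam, at 2184 and 1110.1 CPM (-0.98). Kcnt2 was also above 1.5-fold lower in 4 of 4 other measured classes and Dscam in 5 of 5, but Fgf1 in 1 of 4 and Ndst3 in 1 of 3. Dscam leads cluster 3, which held 77.7% of control and 41.4% of form deprivation cells of this class. Cluster 12, led by Neu4 and Gpr17, held 22.3% and 58.6%. Within clusters 3 and 12 the log2 ratio of Vim was 1.17 and 1.38, of Pgam1 1.03 and 0.81, and of Dscam -0.86 and -0.50.

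The cell cycle list had a median of 0.49 in oligodendrocyte precursor-like cells, with 8 of 17 members above 1.5-fold higher, 2 lower and 7 between, and Pcna, the sliding clamp of DNA replication, was 73.6 and 119 CPM. The reactivity list (0.81, 9 of 15 higher and 1 lower), glycolysis (0.61, 11 of 20 higher), the mitochondrially encoded genes (0.61, 4 of 8 higher), heat shock and dissociation stress (0.54, 3 of 13 higher), ribosomal proteins (0.53, 26 of 81 higher), immediate early genes (0.48, 7 of 22 higher and 1 lower) and the unfolded protein response (0.46, 8 of 18 higher) stood above the random range. Gapdh was 460 and 928 CPM, ATP6 1740 and 3452 CPM, Fos 325 and 591 CPM and Calr 492 and 1016 CPM. The same held for oxidative phosphorylation (0.45, 13 of 38 higher), cholesterol biosynthesis (0.44, 6 of 20 higher), the disease-associated microglia list (0.42, 5 of 15 higher), perineuronal net and extracellular matrix (0.41, 7 of 22 higher and 3 lower) and autophagy and lysosome (0.34, 5 of 24 higher). Fdft1 was 61.0 and 94.9 CPM, Spp1, the matrix protein osteopontin, 219 and 338 CPM, and Sparcl1 1993 and 2663 CPM, although Tnr, a leading gene of cluster 3, was 3732 and 1918 CPM. Ionotropic glutamate receptors (-0.46, 6 of 16 lower), postsynaptic scaffold genes (-0.44, 7 of 22 lower and 2 higher) and TGF-beta signalling (-0.21, 3 of 20 lower and 3 higher) stood below it, with Grik2 at 1232 and 804 CPM, Nlgn1 at 3413 and 2422.5 CPM and Tgfbr1 at 104 and 60.1 CPM. Within clusters 3 and 12 the reactivity median was 0.40 and 0.35, the mitochondrially encoded median 0.68 and 0.19, and the ionotropic median -0.48 and -0.10. The cell cycle median was 0.51 and 0.19, that of immediate early genes 0.24 and 0.38, ribosomal proteins 0.36 and 0.12, oxidative phosphorylation 0.40 and 0.10, cholesterol biosynthesis 0.17 and 0.12, perineuronal net and extracellular matrix 0.42 and 0.05, postsynaptic scaffold genes -0.24 and -0.06 and TGF-beta signalling -0.22 and -0.03, and those of cholesterol biosynthesis and postsynaptic scaffold lay inside the random range in both clusters.

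In endothelial-like cells (505 control and 894 form deprivation cells, median 7532 and 8410.5 UMIs) the lists of immediate early, stress and inflammatory genes were higher in form deprivation, and the median of the blood-brain barrier list was lower with 15 of its 20 members between the 1.5-fold bounds. Adm5, a relative of the vasodilator adrenomedullin, was 66.4 and 288 CPM, a log2 ratio of 2.12 (1.95 to 2.29), Ankrd37, a target of hypoxia-inducible factor, 47.2 and 189 CPM (2.00), and Dnajb1, a heat shock co-chaperone, 164 and 462 CPM. Timp1, a protease inhibitor, Tmem158 and Ctgf, a matrix signalling protein, had log2 ratios of 1.82, 1.70 and 1.69, but 54.3% of control Timp1 UMIs and 59.2% of control Ctgf UMIs lay in 10 cells. Clustering each library separately gave -0.31 for Timp1 and 0.10 for Tmem158, and Ctgf was 2.35 without the 10 cells richest in it. At clustering resolutions of 0.5 and 2, Timp1 was 0.93 and 0.99 and Tmem158 0.48 and 0.52. Both genes are among the leading genes of cluster 26, left unnamed although it scored highest for endothelial cells (3.84). Their ratios therefore depend on which cells the class holds. Lower ratios were those of Agpat4 (-3.12), Kiaa1217 (-1.33), Tmcc3 (-1.32), Crybg3 (-1.32), Corin (-1.31) and Cyyr1 (263 and 113 CPM, -1.21), with 48.6% of control Agpat4 UMIs in 10 cells.

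Of 23 immediate early genes in endothelial-like cells 9 were above 1.5-fold higher and none was lower (median 0.52, random lists -0.22 to 0.17), with Junb at 2342 and 4189.7 CPM. Inflammatory cytokines and NF-kB targets had a median of 0.37 (5 of 15 higher, 3 lower), including the neutrophil attractant Cxcl1 at 1001 and 2243 CPM and Icam1 at 210.1 and 493 CPM. The unfolded protein response (0.32, 6 of 19 higher), glycolysis (0.30, 6 of 20 higher and 1 lower), heat shock and dissociation stress (0.27, 4 of 13 higher), interferon response (0.18, 1 of 14 higher), cholesterol biosynthesis (0.15, 3 of 20 higher and 1 lower) and oxidative phosphorylation (0.10, none of 38 past 1.5-fold) also lay above the random range. Ppp1r15a, which restarts translation after stress, was 512 and 1132 CPM, Gapdh 591 and 1084 CPM, Hspb1 5212 and 8567 CPM, the antiviral gene Rsad2 296 and 589 CPM and Idi1 354 and 567 CPM. The endothelial activation list had a median of 0.21 (2 of 16 higher, 2 lower), with the flow-responsive factor Klf4 at 990.4 and 1420.0 CPM and Vwf, the clotting protein, at 695 and 498 CPM. It was 0.55 after thinning and -0.12 with each library clustered separately. Synaptic vesicle release (0.44, 4 of 10 higher and 2 lower) became -0.05 without doublet removal.

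Blood-brain barrier genes had a median of -0.31 in endothelial-like cells, with 5 of 20 lower, none higher and 15 between, where the median of all genes was -0.11. The most abundant member, Cldn5, the main tight junction protein, was 4899.9 and 5336 CPM, and Mfsd2a, the transporter of omega-3 lipids, 606 and 713 CPM. Wnt signalling, which maintains the barrier, had a median of -0.37 (6 of 21 lower), with Lef1 at 421 and 374 CPM and Gsk3b at 289 and 185 CPM. The mitochondrially encoded genes had a median of -0.44 (2 of 8 lower), with COX2 at 2662 and 1961 CPM. Complement was -0.66 (7 of 12 lower, 2 higher), beside levels of the microglial gene C1qa of 18.2 and 9.01 CPM in this class against 1433 and 2020 CPM in microglia-like cells. Serping1 was 83.3 and 186 CPM.

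In mural-like cells (202 control and 358 form deprivation cells, median 2803.5 and 3791 UMIs) the lists of immediate early genes and of endothelial activation were higher in form deprivation. Icam1 was 92.0 and 390 CPM, a log2 ratio of 2.08 (1.71 to 2.48), and Rgcc, a regulator of the cell cycle, 137 and 415 CPM (1.60), while Nup62cl (1.94) rested on 11 control UMIs. Without the 10 cells of each library richest in the gene these ratios were 3.09 for Icam1 and 3.74 for Nup62cl. They then rested on 24 and 1 control UMIs, against 455 and 30 form deprivation UMIs. Trpc6, a calcium channel of smooth muscle, had a log2 ratio of -2.46, but 93.0% of its control UMIs lay in 10 cells and the ratio was 0.47 without those cells. Cdc27, of the anaphase-promoting complex, was -2.00 and likewise -0.80 without them, and Corin was -1.84. Immediate early genes had a median of 0.73 (15 of 22 higher, none lower), with Junb at 1720 and 3065 CPM, and the endothelial activation list 0.84 (5 of 8 higher, 1 lower), with Klf4 at 191 and 424 CPM. The latter was 1.61 after thinning. Heat shock and dissociation stress (0.52, 4 of 13 higher and 1 lower), the unfolded protein response (0.48, 6 of 16 higher), glycolysis (0.22, 3 of 19 higher and 1 lower), ribosomal proteins (0.17, 1 of 81 higher) and oxidative phosphorylation (0.12, 1 of 38 higher) lay above the random range. Hspb1 was 2943 and 4629 CPM, the stress factor Ddit3 549 and 1105 CPM, Gapdh 1147 and 1449.5 CPM, Rplp1 1591 and 1890 CPM and Ndufa4 720.0 and 771 CPM.

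In neutrophil-like cells (366 control and 290 form deprivation cells, median 2111 and 2644.5 UMIs) genes of sterol synthesis were higher in form deprivation. Cholesterol biosynthesis had a median of 0.67 with 7 of 12 members above 1.5-fold higher and none lower, and Hmgcs1, an early enzyme of the pathway, was 314 and 514 CPM. The unfolded protein response (0.41, 6 of 13 higher), inflammatory cytokines and NF-kB targets (0.30, 6 of 17 higher and 2 lower), glycolysis (0.22, 4 of 15 higher) and oxidative phosphorylation (0.10, 4 of 32 higher and 1 lower) lay above the random range, where the median of all genes was -0.16. Ddit3 was 663 and 1013 CPM, Nfkbia 4554 and 7717 CPM, the glycolytic enzyme Aldoa 671 and 1026 CPM and Ndufa2 142 and 170.4 CPM. The inflammatory median was -0.11 when each cell was weighted equally, and that of oxidative phosphorylation -0.11 with the stricter cell filter. Isg15 (26.7 and 173 CPM, log2 ratio 2.69), the linker histone gene H1-2 (375 and 1472 CPM, 1.97) and the cytokine gene Il24 (2.45) had the largest higher ratios. The largest lower ratios were those of 3 granule genes, Pglyrp1 (-9.59, -14.89 to -7.11), Camp (-7.48) and Ltf (-4.79), but 100% of the control UMIs of Pglyrp1 and Camp and 99.4% of those of Ltf lay in 10 cells. Without doublet removal the log2 ratios were -2.54, -2.01 and -0.49.

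In border macrophage-like cells (113 control and 100 form deprivation cells, median 6274 and 6069 UMIs), which sit in the meninges and around vessels, interferon and inflammatory genes were higher. Interferon response had a median of 0.51 (5 of 11 higher, none lower), with Rsad2 at 488 and 779 CPM and Isg15 at 158 and 340.0 CPM. Endothelial activation (0.38, 2 of 9 higher and 1 lower), inflammatory cytokines and NF-kB targets (0.34, 5 of 18 higher and 1 lower), immediate early genes (0.26, 2 of 20 higher and 1 lower), autophagy and lysosome (0.26, 5 of 23 higher) and the unfolded protein response (0.21, all 14 between the 1.5-fold bounds) lay above the random range. The monocyte attractant Ccl2 was 3373 and 4796 CPM, Ier3 2354 and 3047 CPM, Sqstm1, an autophagy receptor, 281 and 579 CPM and Hspa5 618 and 760.1 CPM. Fam13a (1.77), Dusp2 (1.21) and Cdkn1a, a brake on the cell cycle (1.16), had the largest higher ratios. Fam13a was 0.52 without the 10 cells richest in it. Palld (-2.86), Rbks (-1.63) and Corin (-1.40) had the largest lower ratios, with -1.92 for Palld without doublet removal and -2.68 for Rbks without the 10 cells richest in it. The median of the unfolded protein response was -0.04 without doublet removal. Corin was above 1.5-fold lower in all 8 classes.

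Over the 35 lists and 8 classes, 255 list medians could be computed, of which 65 lay above and 22 below the middle 95% of random lists, against 12.8 expected outside if genes were independent. Genes of a list are correlated, so that number is only a guide. Lists that stood inside the random range in every class ranged as follows: late activity-regulated genes from -0.27 to 0.21, GABA synthesis, transport and receptors from -0.71 to 0.02, hypoxia targets from -0.14 to 0.10, retinoic acid signalling from -0.17 to 0.27, the circadian clock from -0.27 to 0.08, and apoptosis from -0.24 to 0.08.

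**Figure D3:**
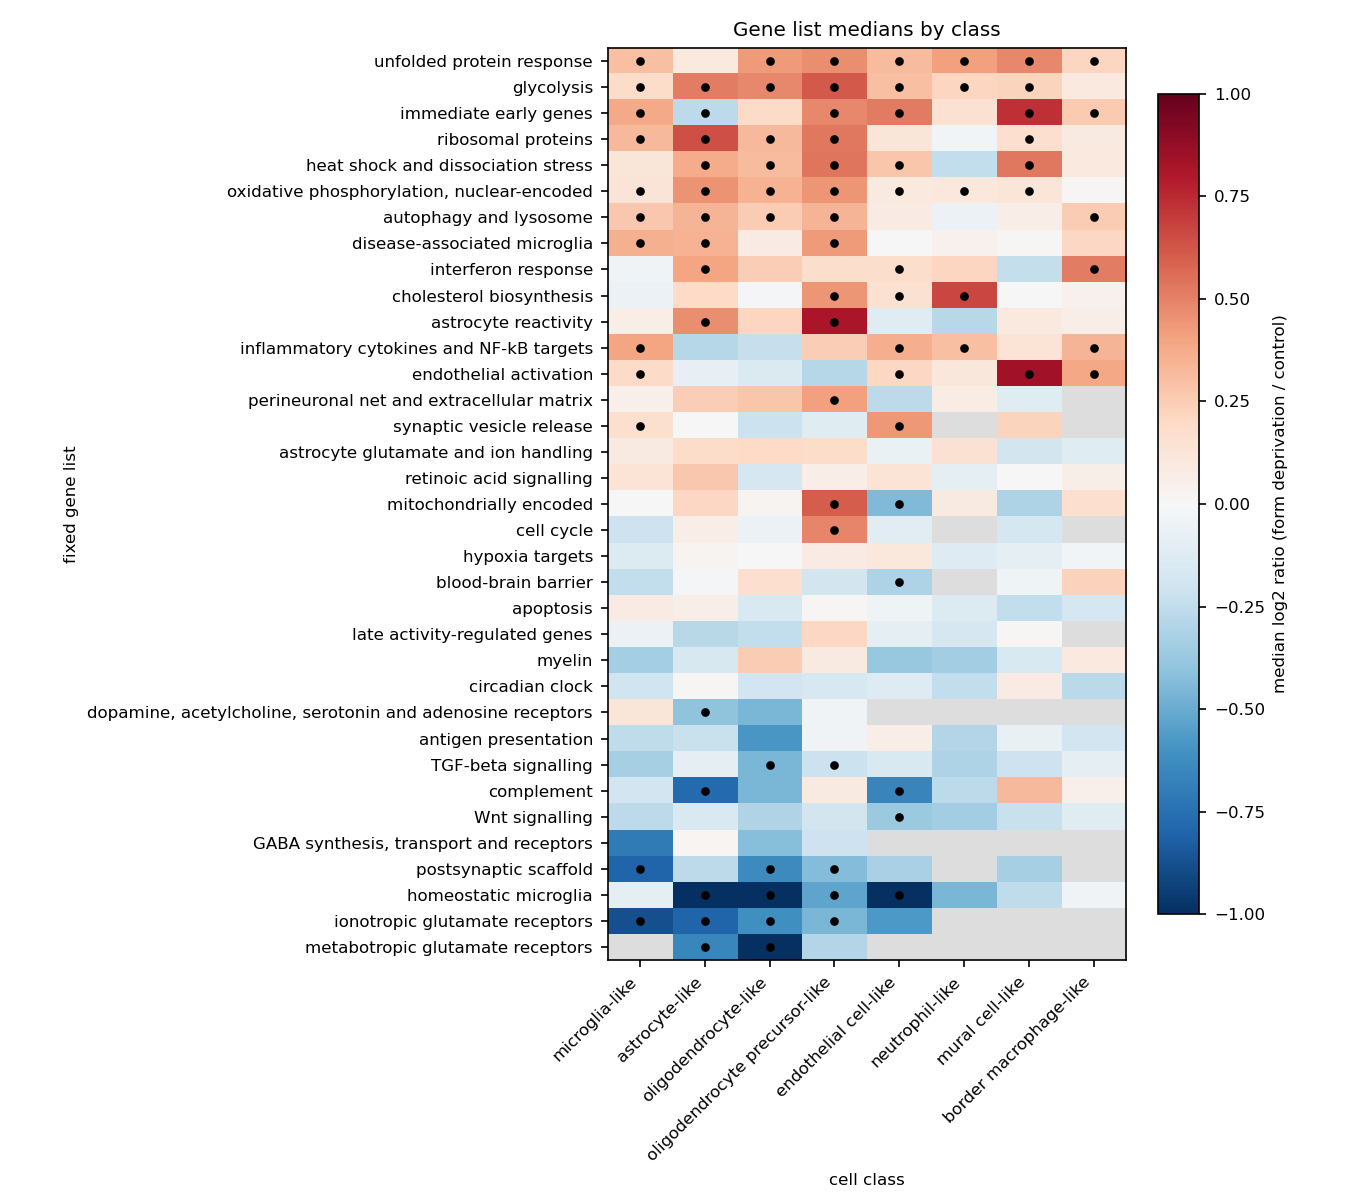
Each field gives the median log2 ratio (form deprivation over control, 1 library each) of a fixed gene list in a class, red where it was higher in form deprivation and blue where it was lower, with colours ending at -1 and 1 and grey where fewer than 5 members were measured. Black dots mark the 87 of 255 medians outside the middle 95% of expression-matched random lists, among them the unfolded protein response in 7 of 8 classes.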

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

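The tests of a different mix of clusters and of less cytoplasmic RNA, given here for the ribosomal protein genes, were chosen after the result had been seen. The bound in the test of cytoplasmic RNA was also tightened once its result was known, because the first bound had argued against that explanation in microglia-like and astrocyte-like cells.

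Some gene lists stood above the middle 95% of random lists in a class and below it in another. The immediate early genes had a median log2 ratio of -0.26 in astrocyte-like and 0.73 in mural-like cells. The mitochondrially encoded genes had a median of -0.44 in endothelial-like and 0.61 in oligodendrocyte precursor-like cells. Neither difference between classes was tested, since each rests on 1 library per group.

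Signals outside the named classes and genes also stood out. Cluster 28, which stayed unnamed, held 1.08% of form deprivation cells (111 cells) and 0.109% of control cells (13 cells), a ratio of 9.88 (5.55 to 19.1). It scored highest for microglia (3.53, with 7 markers raised), against 0.749 for T or NK cells. Its leading genes included Mmp19, Mcpt3, the chemokines Ccl5 and Ccl2, the vasoconstrictor gene Edn1 and Ido1, an interferon-induced enzyme of tryptophan breakdown. Ccl5 was the only fixed marker of T or NK cells among its leading genes and none was a microglial marker, which left the cluster unnamed. LOC106024976, a feature without a symbol, was 50.1 and 368 CPM in astrocyte-like cells, a log2 ratio of 2.88 (2.77 to 2.98). In the other direction, LOC100718133 was 467 and 21.3 CPM in microglia-like cells (-4.46, -4.60 to -4.32), and it leads cluster 4, which came almost wholly from the control library.

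Ribosomal protein genes were higher in form deprivation in several classes, with the highest median, 0.64, in astrocyte-like cells. A different mix of clusters is argued against as the whole cause, because the median over 11 clusters of the 4 glial classes was 0.29 within clusters, with 10 of the 11 above 0.1 and 1, the shallow astrocyte-like cluster 15, at -0.22. Less cytoplasmic RNA in control cells might lower ribosomal and mitochondrially encoded transcripts alike. The mitochondrially encoded median met that in oligodendrocyte precursor-like cells (0.61, 0.28 to 1.09), went against it in mural-like cells (-0.31, -0.77 to 0.03), and left it open in microglia-like (-0.0058, -0.25 to 0.24), oligodendrocyte-like (0.025, -0.10 to 0.46) and astrocyte-like cells (0.21, -0.37 to 0.49). An effect of form deprivation on protein synthesis stays open and untested, as the condition and the library cannot be told apart with 1 library each.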

How the results depend on the processing

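The alternatives that leave out the 10 cells richest in a gene, or the clusters held almost by 1 library, were chosen after the data had been examined. No paired analysis was possible because each group is 1 library. Of the shares of the 8 compared classes, 58 of 67 values under an alternative lay within the interval of the reported value and 9 did not, and of list medians read first in a class 229 of 232 did and 3 did not. Of the other list medians 72 of 3246 moved beyond the interval with the same reading and 1 more reversed. Of named genes 172 of 1087 moved and 2 more reversed. The sign differed from the reported one for 5 of these shares, 19 of the list medians read first and 260 of the others, and for 2 named genes. The interval of the reported value included 0 in each case but 3, which are the 2 genes and 1 of the other list medians. For the log2 ratio of shares, counting within neurons and ectoderm-derived glia gave 0.22 for astrocyte-like (0.46 as reported), 0.071 for oligodendrocyte-like (0.31) and -0.79 for oligodendrocyte precursor-like cells (-0.56), since this denominator leaves out the microglia-like cells. The stricter cell filter gave -1.45 for oligodendrocyte precursor-like cells, where a cluster was left without a name, and 0.24 for neutrophil-like cells (-0.13). Microglia-like cells were at -0.58 at resolution 0.5, -0.61 at resolution 2 and -0.62 without a cell filter (-0.69), and endothelial-like cells at 0.61 with each library clustered separately (1.03). Among list medians, antigen presentation in microglia-like cells was -0.032 without the clusters held almost by 1 library (-0.25), cell cycle in microglia-like cells 0.52 with each library clustered separately (-0.20), and endothelial activation in endothelial-like cells 0.55 after thinning (0.21). The 3 results that changed sign although their reported interval excluded 0 were Timp1 in endothelial-like cells with separate clustering (-0.31 against 1.82), Trpc6 in mural-like cells without the 10 cells richest in it (0.47 against -2.46), which held most of its control UMIs, and ribosomal proteins in border macrophage-like cells with each cell weighted equally (-0.051 against 0.09). Except where a reason is given, the cause was not tested. Leaving out the 10 richest cells gave no value for Pglyrp1, Camp, Ltf and Palld, which had no UMI left in a library, and oxidative phosphorylation in neutrophil-like cells had too few members at 100 counts. The ratio of cycling-like cells was 8.21 at resolution 0.5, where they merged with the neuroblast-like cells. Depth limits the mural-like and neutrophil-like classes most, with control medians of 2803.5 and 2111 UMIs in 202 and 366 cells, whereas border macrophage-like cells are limited by their number, 113 and 100 cells.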

Other observations

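Of the tests given here, those of a shift of all control microglia, of an interferon-gamma response and of Dlx1 were chosen after the result had been seen. The reading of Ttr on its own was not fixed beforehand either. Several clusters that stayed unnamed differed in share between the libraries. Cluster 26, led by Ccl21, Ackr1, a chemokine receptor of venules, the adhesion gene Vcam1, Ptgs2, Timp1 and Tmem158, held 0.469% of control and 0.824% of form deprivation cells, a ratio of 1.76 (1.24 to 2.51). Cluster 19, led by the pericyte gene Rgs5, Atp13a5 and Fn1, held 0.603% and 1.39% (2.30, 1.72 to 3.09), so vessel genes led these unnamed clusters too, in the same direction as the named vessel classes. Cluster 19 scored 4.07 for endothelial and 2.83 for mural cells, at a median of 13724 UMIs against 8151 in the endothelial-like cluster. Doublets of these classes are therefore left open, and its share is no separate evidence for more vessel cells. Cluster 17, led by Rasgef1b, Icam1 and Nfkb1, held 1.22% and 1.85% (1.51, 1.21 to 1.89). Lower shares were those of cluster 23, led by Nfasc, Bcas1 and Enpp6, genes of newly formed oligodendrocytes, at 0.955% and 0.591% (0.619, 0.446 to 0.852), and of cluster 18, led by the granule genes Mpo and Gncp-1b, at 1.45% and 0.785% (0.542, 0.411 to 0.709).

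The neuroblast-like cluster was led by Robo2, Igfbp5, Reln, Tnc, Stmn2 and Dcx, and carried genes of inhibitory neuron precursors. Dlx1, a transcription factor of that lineage, was 78.4 CPM in it and 0 in control oligodendrocyte precursor-like cells, Dlx2 113 and 0.165 CPM, and Gad2 65.8 and 0.987 CPM. The neuronal genes Stmn2 and Tubb3 were 268 and 16.04, and 614 and 42.7 CPM, while Dcx, at 422 and 158 CPM, was also present in the precursors.

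Neuroblast-like and ependymal-like cells came almost only from the form deprivation library. A loss of control ependymal-like cells to the processing is argued against, since 1 control barcode of all deposited (0.0253 to 5.57) carried at least 4 of 7 ependymal markers, against 53 form deprivation barcodes. A piece of tissue with choroid plexus as well as ventricular wall stays open. The abundant choroid plexus gene Ttr had 2 and 0 UMIs in all other cells. However, the test fixed beforehand was the sum of the choroid plexus markers and not Ttr alone. Whether Ttr can be counted with this annotation was not checked. The summed choroid plexus markers had a log2 ratio of 0.015 (-0.18 to 0.21). That sum cannot decide the question, since Folr1 (245 and 354 UMIs) and Kl (206 and 58) made up most of its 491 and 421 UMIs and went opposite ways. A loss of control neuroblast-like cells stays open: 71 control barcodes (55.5 to 89.6) carried at least 4 of the 5 measured neuroblast markers, of which 43 lay among oligodendrocyte precursor-like cells and 25 were removed before clustering. In the form deprivation library 135 barcodes did, of which 23 lay among those precursors, 29 were removed and 73 lay in the neuroblast-like cluster. Dlx1 had 18 UMIs (10.7 to 28.4) over all control barcodes against 167, and without doublet removal the cluster held 28 control and 233 form deprivation cells. Ventricular wall without choroid plexus, which may have come with the dissected piece, and an effect of form deprivation stay open and were not tested.

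Microglial clusters 4 and 10 came almost wholly from the control library, with 1510 and 950 control cells against 10 and 39. A technical shift of all control microglia stays open: the 49.6% of them (48.1 to 51.0%) that lay in clusters shared by both libraries are the rest of the pattern itself and decide nothing. Within shared clusters 1, 2 and 13 Agpat4 still had log2 ratios of -6.60, -5.51 and -4.12, the last on 2 form deprivation UMIs. Only 7.79% of control microglia-like cells held an Agpat4 UMI, so this gene cannot speak to a shift of all of them. Of 18 interferon-gamma targets, listed after the data had been examined, 15 were in the files, and their median log2 ratio was -0.75 (-1.55 to -0.15) in microglia-like cells. A response of the whole control tissue stays open, with medians of 0.041 (-0.43 to 0.25) in endothelial-like, -0.09 in astrocyte-like, 0.01 in oligodendrocyte precursor-like and -0.05 in mural-like cells. These clusters may also come from 1 or a few of the 6 pooled animals, which could not be tested without a map from cells to animals, and an effect of form deprivation stays open and untested.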
